A study of Homo sapiens with 15 samples.

How the data were processed

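The samples are 15 libraries of the human melanoma line A375 in 5 groups of 3: Parental, Resistant (a population resistant to PLX4720), Parental with MYC T58A, and Resistant labelled with shMYC1 or shMYC2. According to the labels, cells were grown in normal culture and harvested before full confluency, RNA was extracted with a Qiagen RNeasy kit and stranded mRNA libraries were made with a Kapa kit. Drug exposure at harvest is not given. The submitters name Trim Galore, cutadapt, STAR, HTSeq and DESeq2 (no version given). The genome build, the annotation and the strand counted are not given in the sources used here.

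The deposited table holds signal values per gene symbol, which as deposited are read counts divided by a size factor for each library. This unit was read from the values, since the authors' notes name DESeq2 but do not state it. Each column was found to be whole multiples of a single step (0.881 to 1.08), so whole reads could be recovered for 100% of values within a tolerance of 0.01. The size factors recomputed from the recovered reads differed from the steps by at most 0.019%. Every gene in the table reaches at least 10 reads in its highest library, so genes below that are not analysed here. Libraries are numbered in the order of the table's columns.

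The plan, written before the data were examined, expected read counts and gave a second test for normalized values, which was used. Values were transformed to log2(value + 1), and genes with a value of at least 10 in at least 3 libraries were kept (17012; 1310 were left out). A linear model with a mean for each of the 5 groups was fitted to all 15 libraries with limma 3.58.1 (trend and robust) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes were called at an adjusted p under 0.05. Log2 differences on this scale understate the change of genes with few reads. The adjusted p-values describe differences between the 3 libraries of each group, and since resistance comes from a single clonal population they carry no variation between independent resistant populations. For genes with no read in a whole group, a fold is given as a lower bound that takes 3 reads in each library of that group. Where a group had reads but a mean under that level, the ratio of the means is given with an exact 95% Poisson interval. That interval covers counting alone and not variation between libraries.

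As a check on the choice of test, the recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. edgeR called 9253, 11164, 10148 and 13499 genes in Resistant against Parental, MYC T58A against Parental, and the libraries labelled shMYC1 and shMYC2 against Resistant, and DESeq2 called 8854, 10847, 9813 and 13629. The main test was tested on simulated data of the same depth, with 50 genes changed at each fold, all with a mean of at least 50 in the reference group. It recovered 88% to 98% of genes changed 1.5-fold, at least 98% of those changed 2-fold, 4-fold or 8-fold, and 3.94% to 6.76% of its calls were false. All other simulated genes were left unchanged, whereas most tested genes were called in each main comparison. These rates may therefore not carry over to the data.

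Gene lists were fixed from general knowledge before the table was opened. There were 34, of which 27 were for programmes that could change in these cells, 5 for markers of other cell types and 2 for RNA quality. Lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01 between members, adjusted over lists within a comparison. Camera with an estimated correlation and fry were run beside it.

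Genes are named by a rule fixed in advance. It names MYC, and the 5 largest increases and decreases of each main comparison among called genes with a mean of at least 10 CPM (counts scaled to a common library total) and no overlap between the groups' libraries. It also names up to 3 called members of a list in its main direction and 1 in the other, the 5 genes with the largest smaller change in each direction of an overlap, and BRAF, NRAS, EGFR, AXL, SRC, MITF and DUSP6. KIT was also fixed and is not analysed here. CIITA, CD74, HLA-DRA, HLA-DPA1, HLA-DMA and MTAP were added after their values were seen.

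Overlaps of calls were set beside those of independent lists, and correlations of log2 differences beside 20 simulated data sets in which no gene changes and controls are shared. Windows of at least 50 neighbouring genes were ordered by GENCODE v29, which was used for gene order alone, and their medians were set beside 100 random gene orders. The alternatives planned were quantile normalization, other filters, pseudocounts of 0.1 and 10, limma without robust, DESeq2, the libraries compared alone, leaving out each library, an adjusted p under 0.01 and a minimum change of 0.5. Chosen after the data were examined were edgeR, total-count scaling, fits without the libraries labelled shMYC2, shMYC1 alone, and list tests on values less the median shift of each window in each library. The shift was measured against each gene's mean over all libraries. The 13694 genes with a place on chromosomes 1 to 22 were shifted and the others left as they were. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.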

Results

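RNA was sequenced from A375, a human melanoma cell line that carries an activating BRAF mutation, in 5 groups of 3 libraries, which the series describes as biological triplicates. The groups were the parental line (Parental), a clonal population resistant to PLX4720 (Resistant), parental cells with MYC T58A, and resistant cells labelled with either of 2 short hairpins against MYC (shMYC1 and shMYC2). PLX4720 is an inhibitor of mutant BRAF, the kinase that drives the MAPK pathway in these cells. MYC is a transcription factor that raises the expression of growth genes, and its T58A form is degraded more slowly than the wild type. The title of the series places MYC at the centre of how melanoma cells come to resist the drug, so the comparisons ask what differs in the resistant cells, what MYC T58A changes in parental cells, and what each hairpin changes in resistant cells.

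Values are normalized read counts, given as mean ± SD of 3 libraries. The 3 Parental libraries held 24812116 to 25202625 reads in genes, those of Resistant 24222192 to 28036807, those labelled shMYC1 28212113 to 30399644, those labelled shMYC2 26332818 to 27817945 and those of MYC T58A 24415163 to 28227222. The table gives 18322 genes, of which 17012 were tested. Libraries of the same group correlated across genes at r = 0.991 to 0.995, and no pair of them differed by as little as sampling noise allows (lowest chi-square per gene 1.65, where noise alone gives about 1). Library 2 labelled shMYC1 stood furthest from its own group, at 29.1 and 19.8 against libraries 1 and 3, where no other pair within a group passed 8.05. Parental libraries correlated with those labelled shMYC1 at r = 0.972 to 0.974, above their correlation with Resistant libraries (0.95 to 0.952). The Resistant libraries, which the labels give as the source of the shMYC1 cells, correlated with those labelled shMYC1 at 0.937 to 0.942. The libraries labelled shMYC2 stood apart from the other 12, with r = 0.807 to 0.829. In them 1636 to 1694 of the 18322 genes had no read, against 296 to 665 in the other libraries. Genes are not independent replicates, so these correlations describe the libraries and carry no p-value.

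**Figure D1:**
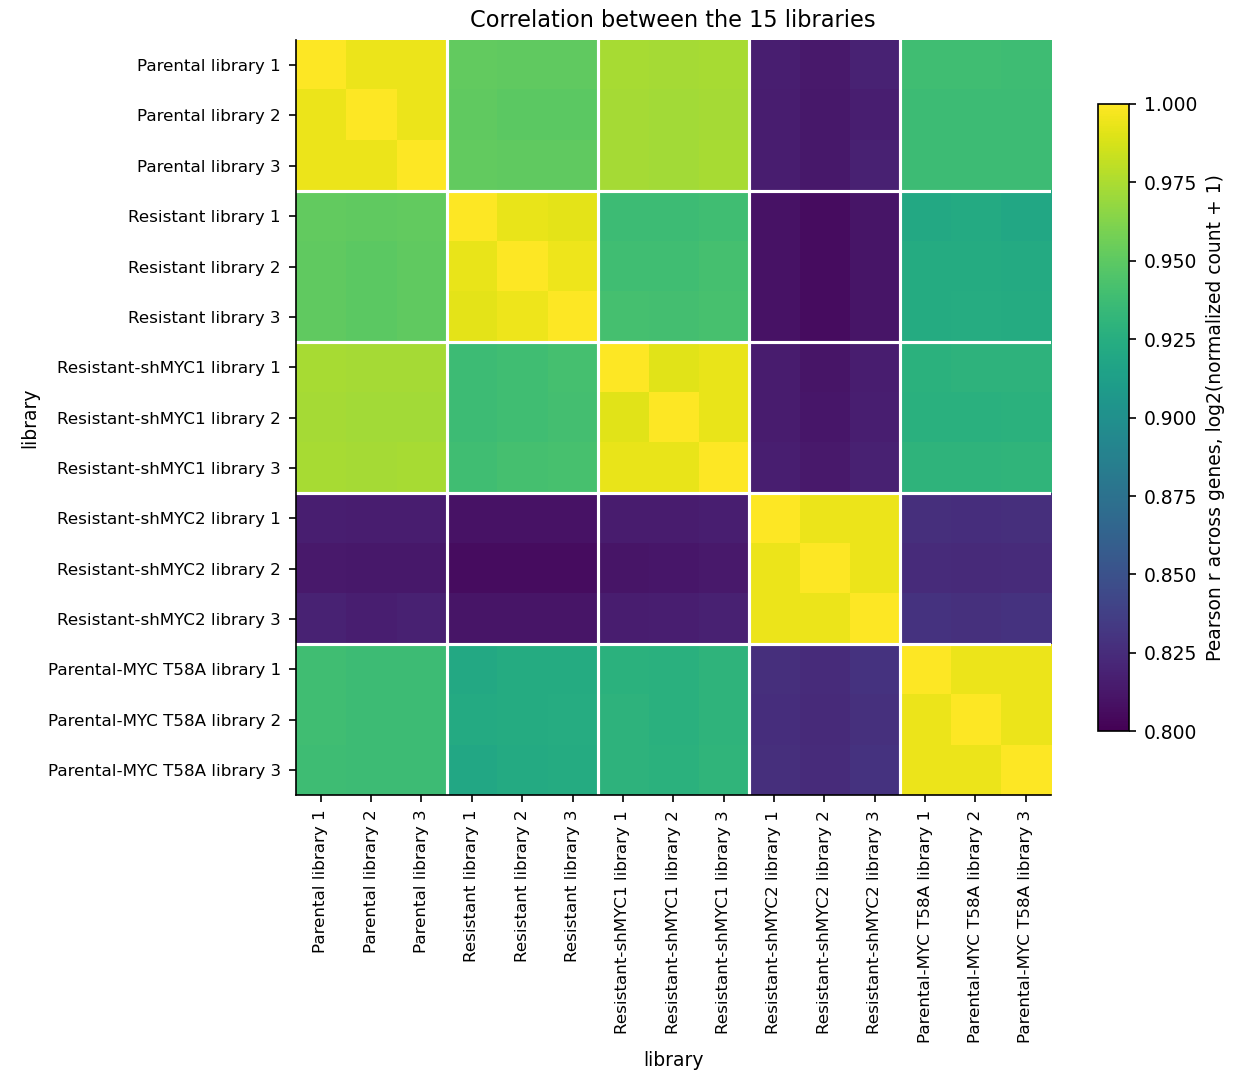
Pearson correlation across genes of log2 normalized read counts (plus 1) between every pair of the 15 libraries, grouped as labelled. Blocks of the same group lie at 0.991 to 0.995, the libraries labelled shMYC1 lie nearer to Parental (0.972 to 0.974) than to Resistant (0.937 to 0.942), and the libraries labelled shMYC2 lie at 0.807 to 0.829 from all others.

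MYC itself went against the labels of both hairpins. Its transcript stood at 422.7 ± 11.9 normalized reads in Parental, 302.5 ± 28.1 in Resistant, 486 ± 29.5 in the libraries labelled shMYC1, 7817 ± 260 in those labelled shMYC2 and 3511 ± 94.4 in MYC T58A. MYC was thus 1.61-fold higher in the libraries labelled shMYC1 than in Resistant (log2 difference 0.68, SE 0.064, adjusted p = 4.43e-08) and 25.8-fold higher in those labelled shMYC2 (4.69, SE 0.064, adjusted p = 1.74e-20). It was 8.29-fold higher in MYC T58A than in Parental (3.05, SE 0.064, adjusted p = 5.82e-17), where reads of the construct and of the cell's own gene are counted together. It was 1.4-fold lower in Resistant than in Parental (-0.49, SE 0.064, adjusted p = 4.32e-06). Against Parental, MYC was 1.15-fold higher in the libraries labelled shMYC1 (0.2, SE 0.064, adjusted p = 0.0187). That last call was lost without Parental library 2 or 3 or library 2 labelled shMYC1 (0.15 to 0.24 over the libraries left out), and under total-count scaling (0.14). The libraries of the groups did not overlap in any of these 5 comparisons, but an exact two-sided permutation test of 3 libraries against 3 cannot go below p = 0.1. No lower MYC transcript level stands behind either hairpin label, so the hairpin comparisons are given below as differences between labelled libraries.

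**Figure D2:**
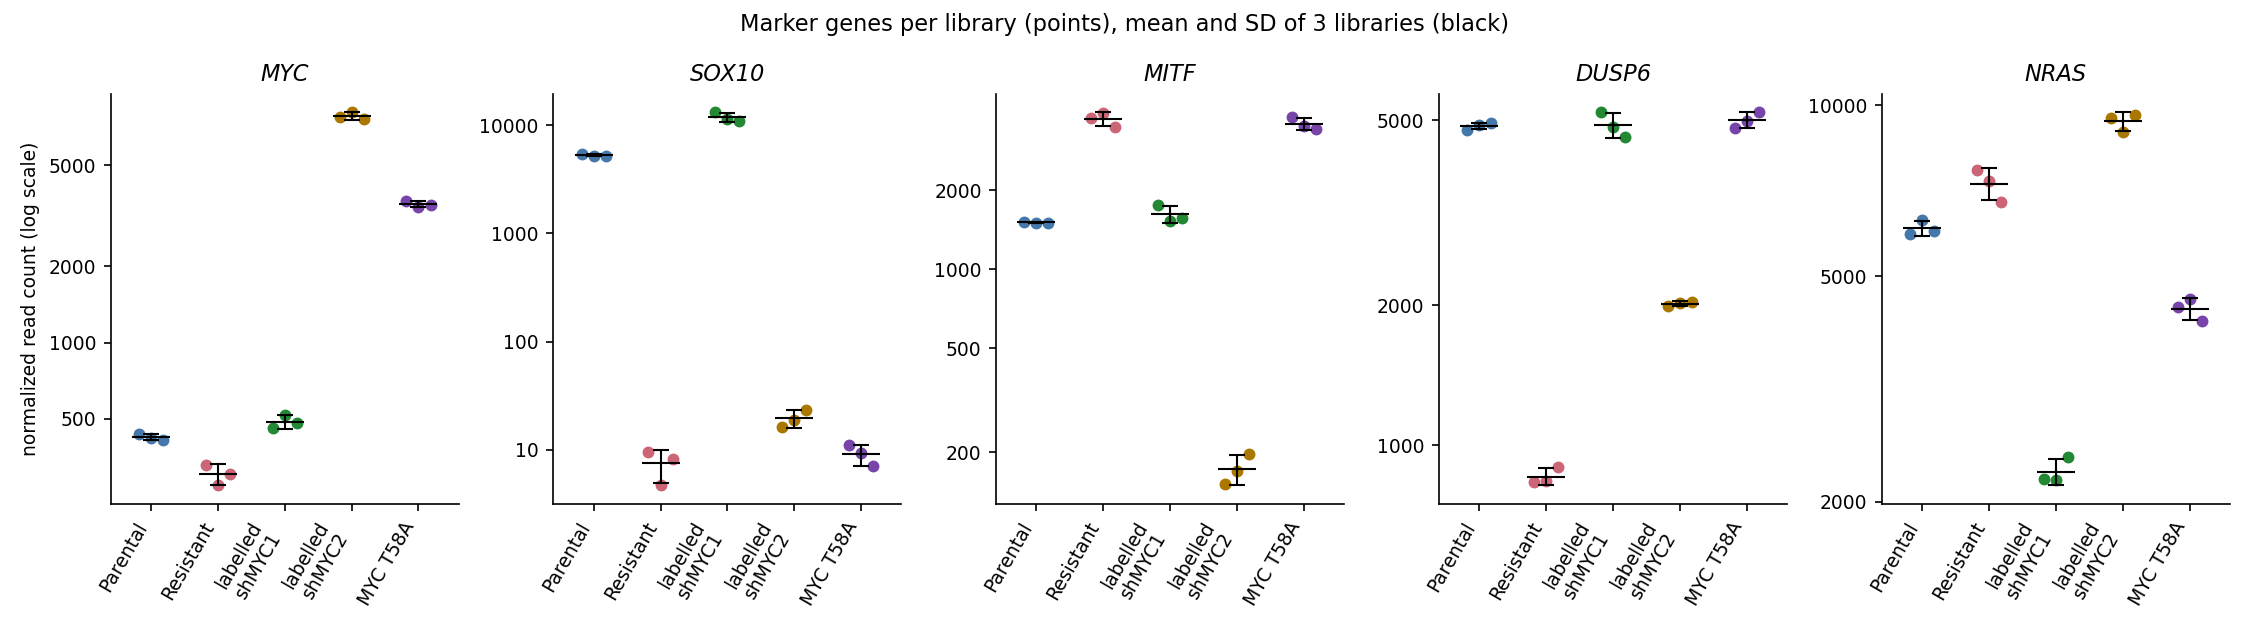
Normalized read counts (log axis) of MYC, SOX10, MITF, DUSP6 and NRAS in each of the 15 libraries, with points for libraries and bars for the mean ± SD of each group of 3. MYC is highest in the libraries labelled shMYC2 (7817) and in MYC T58A (3511), and SOX10 is near 0 in Resistant (7.5), MYC T58A (9.14) and the libraries labelled shMYC2 (19.48) but at 11890 in those labelled shMYC1.

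Resistant cells had all but lost SOX10, the transcription factor that maintains the melanocyte and neural crest lineage, which fell 642-fold from 5282 ± 149 to 7.5 ± 2.52 normalized reads (log2 -9.33, SE 0.2, adjusted p = 2.4e-15). By list, targets of the amino acid stress response rose, a call that held when the correlation between members was estimated (adjusted p = 0.0276). DUSP6, a phosphatase that the MAPK pathway induces against ERK, was down 5.68-fold from 4865 ± 79.4 to 856.9 ± 36.1 (-2.5, SE 0.049, adjusted p = 1.16e-16). MITF, the pigment cell master regulator, went the other way and rose 2.48-fold to 3748 ± 233 (1.31, SE 0.079, adjusted p = 2.25e-10). The genes that rose most were KIAA1462, a cell junction protein (87.8-fold), C9orf84, a meiosis gene (61-fold), LCP1, an actin-bundling protein of blood cells (49.9-fold), the receptor tyrosine kinase ROS1 (44.8-fold) and the stress protein NUPR1 (39.1-fold). Those that fell most after SOX10 were GAS7, which binds actin (148-fold), TMPRSS15, which encodes enteropeptidase (132-fold), the pseudokinase TRIB2 (122-fold) and the galactosidase relative GLB1L2 (57.2-fold).

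By list, 11 of 15 neural crest and glial genes were lower in Resistant than in Parental and 3 were higher (11 and 4 when adjusted over the list alone; median log2 -1.41, camera adjusted p = 0.00178, adjusted p = 0.235 with an estimated correlation). SOX2, a stem cell factor, fell 123-fold (95% interval from counting alone 64.3 to 269), and the neural crest factor TFAP2B from 202.9 to no read, at least 69.5-fold, whereas the adhesion molecule NCAM1 rose 8.26-fold. Of 25 melanocyte genes 8 rose and 9 fell, the same numbers adjusted over the list alone, with no call for the list (adjusted p = 0.547). S100B, a glial and melanocyte calcium sensor, fell 22.6-fold, while the lipid carrier APOE rose 7.28-fold. MAPK output genes fell in 21 of 34 cases and rose in 5, also adjusted over the list alone (median -0.7, adjusted p = 1.82e-05, adjusted p = 0.19 with an estimated correlation). The immediate early genes EGR3 and EGR1 fell 142-fold (counting interval 48.4 to 694) and 18.5-fold, and BMF, which promotes cell death and is held down by ERK, rose 7.97-fold.

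The NF-kB and inflammatory secretion genes rose in 19 of 23 cases and fell in 4 (also over the list alone; median 1.23, camera adjusted p = 1.22e-05, adjusted p = 0.0724 with an estimated correlation). The chemokine CCL2 rose 10-fold to 4019 ± 129, the cytokine IL6 9.83-fold to 2502 ± 52.1 and the prostaglandin enzyme PTGS2 7.26-fold, while the cytokine IL1A fell 9.24-fold. Of 39 interferon response genes 24 rose and 4 fell (also over the list alone; median 0.54, adjusted p = 8.74e-05, held at adjusted p = 0.0276 with an estimated correlation). The guanylate-binding proteins GBP2 and GBP1 rose 4.62-fold and 3.5-fold, and IFI44L 4.22-fold, while the interferon regulator IRF7 fell at least 21.9-fold to no read. Of 25 targets of ATF4, the factor of the amino acid response, 21 rose and 3 fell (also over the list alone; median 0.64, adjusted p = 5.35e-07, held at adjusted p = 0.0276 with an estimated correlation). Besides NUPR1 they included CHAC1, which degrades glutathione (6.39-fold), and the transcription factor JDP2 (6.08-fold), with DDIT4, an inhibitor of mTORC1, 1.66-fold lower. Lysosome and autophagy genes rose in 15 of 29 cases and fell in 5 (also over the list alone; adjusted p = 0.0374, adjusted p = 0.345 with an estimated correlation). The protease CTSK led them (15.1-fold), with the enzyme GUSB 1.22-fold lower. Apoptosis regulators rose in 13 of 26 cases and fell in 4 (also over the list alone; adjusted p = 0.0374, adjusted p = 0.228 with an estimated correlation). They included both the inhibitor of cell death BIRC3 (5.84-fold higher) and its promoter BBC3 (2.99-fold higher), with the survival gene BCL2L1 1.73-fold lower. These last 2 calls also depended on single libraries: that of lysosome genes was lost without Parental library 1 (adjusted p = 0.0525) and that of apoptosis regulators without Parental library 2 (0.052).

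Other lists were lower in Resistant by smaller amounts. Of 57 MYC targets 29 fell and 3 rose (also over the list alone; median -0.15, camera adjusted p = 0.00124, held at adjusted p = 0.0276 with an estimated correlation). ODC1, which starts polyamine synthesis, fell 1.78-fold, the nucleolar protein NPM1 1.57-fold and TCOF1, which supports ribosomal RNA synthesis, 1.54-fold. Of 36 mitosis genes 21 fell and 3 rose (also over the list alone; adjusted p = 9.82e-05, adjusted p = 0.261 with an estimated correlation). The phosphatase CDC25B fell 2.17-fold and cyclin B1, CCNB1, 2.01-fold. Lists of the mitochondrial ribosome (18 of 44 lower, 2 higher, also over the list alone), the proteasome (16 of 30 lower, 1 higher; 18 and 1 over the list alone), chaperones (17 of 30 lower, 4 higher; 18 and 4 over the list alone) and sterol synthesis (11 of 28 lower, 3 higher; 10 and 3 over the list alone) were also lower. Their adjusted p were 0.00122, 0.00119, 0.004 and 0.0367, and all 4 calls were lost with an estimated correlation (adjusted p = 0.438, 0.433, 0.467 and 0.235). Not called were ribosome biogenesis (adjusted p = 0.139), cytosolic ribosomal proteins (0.232), glycolysis (0.547), nucleotide and one-carbon synthesis (0.789), and G1/S and DNA replication (16 of 43 higher, 9 lower; 0.444). Examples of the called lists are MRPS30 of the mitochondrial ribosome (1.98-fold), the proteasome subunit PSMA7 (1.78-fold), the chaperonin subunit CCT5 (1.68-fold) and the desaturase SCD (4.69-fold). Apart from SCD, all of these named genes lie in regions that were lower as a whole. NPM1, TCOF1, CCNB1, MRPS30 and CCT5 are on chromosome 5 (median of all its genes -0.5), CDC25B and PSMA7 on chromosome 20 (-0.36), and ODC1 in a window of chromosome 2 with a median of -0.64. In ODC1 (-0.83), NPM1 (-0.66) and TCOF1 (-0.62) little of the fall went beyond that of their windows (-0.64, -0.54 and -0.54). With the shift of each window of neighbouring genes taken off, all 13 lists called in Resistant were called the same way, MYC targets at adjusted p = 0.0051 (median -0.13), chaperones at 0.0478 and sterol synthesis at 0.0415. A list not called before was gained, which made 14.

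In all, 8781 genes (51.6%) differed between Resistant and Parental, 4623 higher and 4158 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 1373 and 1053 of them by at least 1 on the log2 scale. The libraries did not overlap for 10800 genes (63.5%, where chance gives 10%). Of the genes fixed for every comparison, NRAS was 1.2-fold higher, EGFR 1.24-fold lower and SRC 1.17-fold lower (log2 -0.23, where the median of its window was -0.28), and BRAF (adjusted p = 0.328) and the receptor AXL (adjusted p = 0.954) did not pass the test. Markers of other cell types moved both ways: the fibroblast genes FAP, ACTA2 and COL15A1 were 16-fold, 8.86-fold and 7.56-fold higher but PDPN 51.8-fold lower (counting interval 8.86 to 2090). The epithelial gene ELF3 was 52.2-fold higher (25.1 to 131) but KRT14 38.8-fold lower (19.4 to 90.6). Neither the fibroblast list nor the keratinocyte list was called (adjusted p = 0.547 and 0.759), nor were the endothelial markers (0.547), the mitochondrially encoded transcripts (0.925) or the histones (0.486), and 3 immune markers were too few to test as a list. Only 2541 genes were called against a minimum change of 0.5 on the log2 scale.

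**Figure D3:**
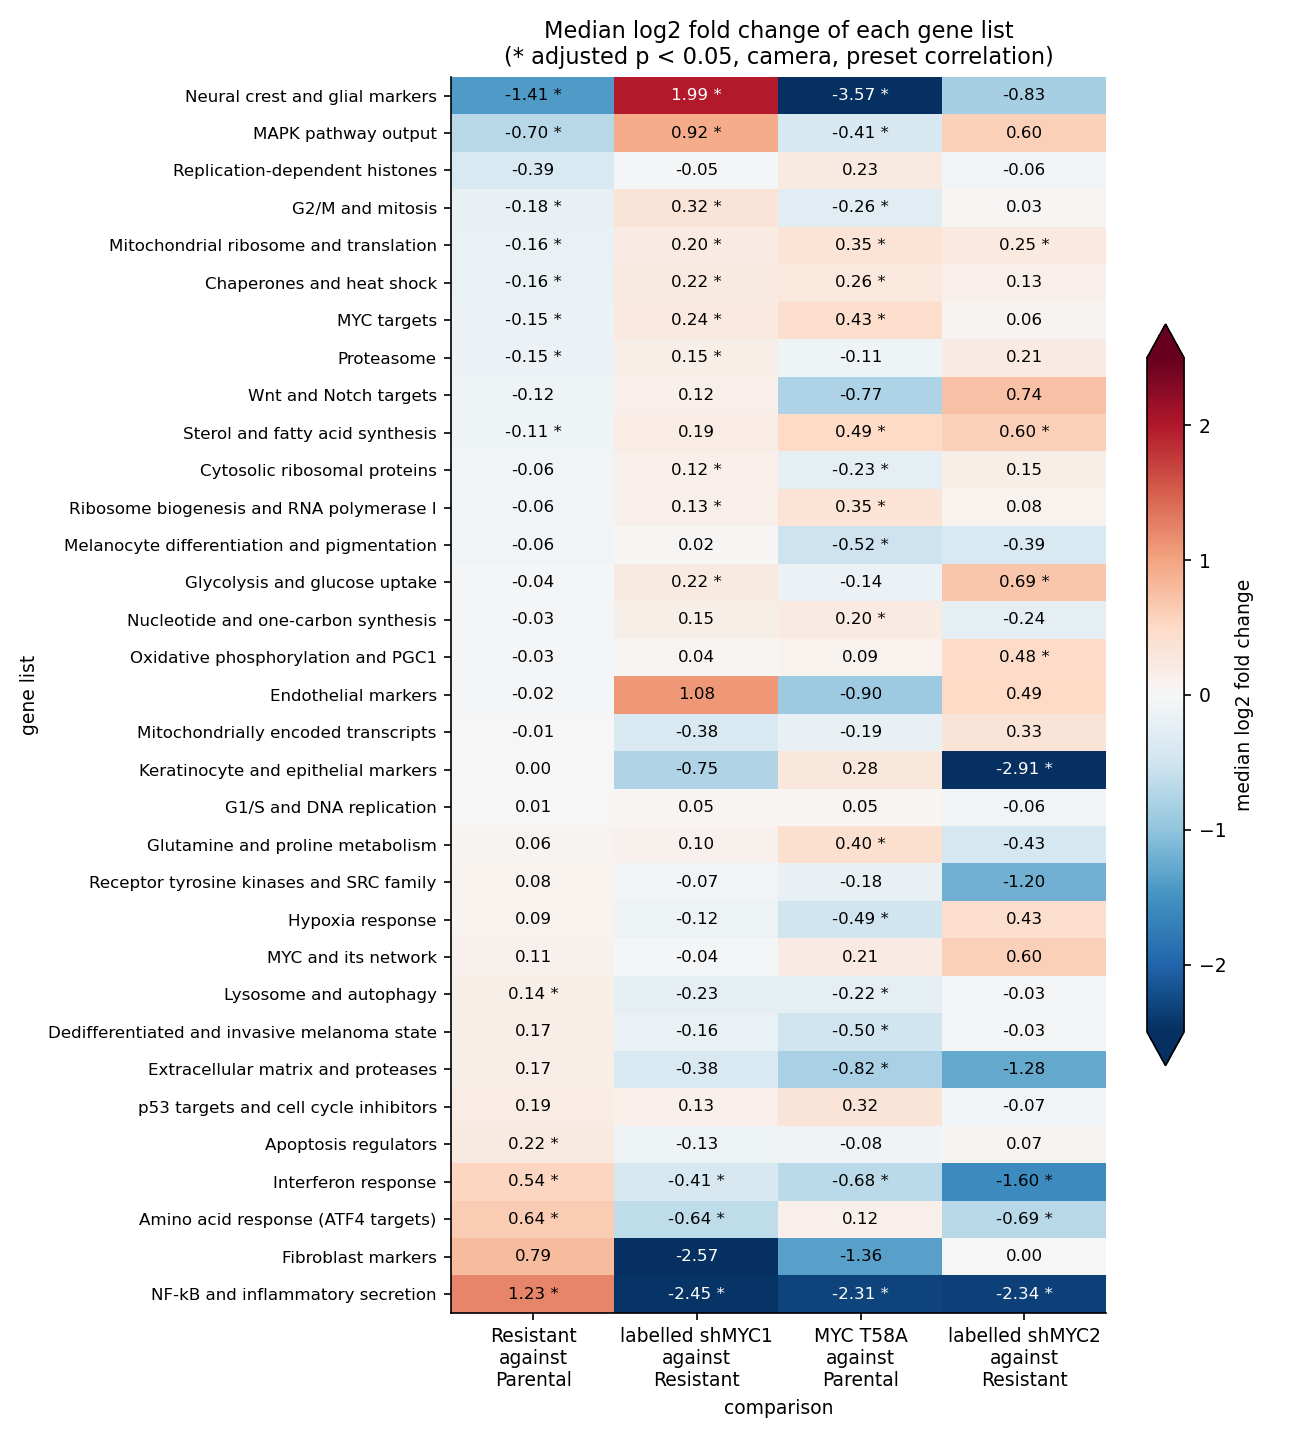
Median log2 difference (colour and cell text) of the tested members of 33 gene lists (vertical axis) in the 4 main comparisons (horizontal axis). An asterisk marks an adjusted p of camera under 0.05. NF-kB genes are higher in Resistant than in Parental (1.23) and lower in the other 3 comparisons (-2.31, -2.45 and -2.34), and of the lists marked, cytosolic ribosomal proteins in the libraries labelled shMYC1 changed sign under another scaling (0.12, and -0.01 with quantile normalization).

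MYC T58A cells shared the loss of SOX10, which fell 528-fold to 9.14 ± 1.99 normalized reads (log2 -9.04, SE 0.2, adjusted p = 1.56e-15), while the list of MYC targets rose and that of the extracellular matrix fell (adjusted p = 0.00414 and 0.0367 with an estimated correlation). EPHA3, an ephrin receptor, fell 3660-fold (counting interval 1010 to 30200) from 2297 ± 107 to 0.628 ± 0.547. The netrin receptor UNC5D fell from 814 ± 68 to no read (at least 279-fold), the retrotransposon-derived gene RTL1 2970-fold (533 to 117000, from 1 read in the 3 libraries) and the transcription factor RUNX3 330-fold. The genes that rose most were RP11-64D22.2, a gene known by its clone name (504-fold, counting interval 216 to 1550, to 873 ± 62.7), the cancer-testis antigen MAGEB2 (46.1-fold), the growth factor BMP5 (40.1-fold) and LPAR1, a receptor for lysophosphatidic acid (31.4-fold). AL161626.1 also ranked among them, at 3596 ± 2530 against 60.11 ± 12.5 (5.55, SE 1.2, adjusted p = 0.00193), with a spread between libraries nearly as large as its mean.

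Of 57 MYC targets 39 rose in MYC T58A and 7 fell (also over the list alone; median 0.43, camera adjusted p = 5.45e-07, held at adjusted p = 0.00414 with an estimated correlation). The telomerase gene TERT rose 5.11-fold, the glycolytic enzyme HK2 2.39-fold and the ribosome assembly gene BOP1 2.28-fold, while PA2G4 fell 1.42-fold. Of 46 genes of ribosome biogenesis and RNA polymerase I 37 rose and 3 fell (39 and 3 over the list alone; adjusted p = 5.32e-07, adjusted p = 0.074 with an estimated correlation). RRP1B rose 2-fold and NAT10 1.88-fold, and NOC2L fell 1.34-fold. The cytosolic ribosomal protein genes themselves fell in 35 of 65 cases and rose in 2 (34 and 2 over the list alone; median -0.23, adjusted p = 0.00467, adjusted p = 0.709 with an estimated correlation). RPL11 fell 1.66-fold and RPL9 rose 1.27-fold. Mitochondrial ribosome genes rose in 30 of 44 cases and fell in 4 (also over the list alone; adjusted p = 3.37e-05, adjusted p = 0.241 with an estimated correlation), MRPS30 by 2.07-fold, with MRPL24 1.82-fold lower. NOC2L, RPL11 and MRPL24 are on chromosome 1, where all genes together were lower in MYC T58A (median -0.46). NOC2L (-0.43) and RPL11 (-0.73) fell about as much as their windows did (-0.42 and -0.75), and MRPL24 (-0.86) somewhat more (-0.63).

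Further lists were higher in MYC T58A than in Parental, though not glycolysis (adjusted p = 0.27), oxidative phosphorylation (0.135) or G1/S and DNA replication (0.841). Of 28 sterol and fatty acid synthesis genes 20 rose and 3 fell (also over the list alone; adjusted p = 0.000168, adjusted p = 0.0503 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose 2.68-fold and CYP51A1 2.67-fold, and PMVK fell 1.7-fold. DHCR7, the final enzyme of cholesterol synthesis, was 3.15-fold higher (adjusted p = 0.0209), a call lost with a pseudocount of 0.1. Glutamine and proline genes rose in 17 of 25 cases and fell in 4 (also over the list alone; adjusted p = 0.00131, adjusted p = 0.0854 with an estimated correlation), with the serine pathway enzyme PSAT1 2.03-fold and asparagine synthetase ASNS 1.73-fold higher. Glutamine synthetase GLUL fell from 70.02 ± 6.74 to 0.334 ± 0.578, a ratio of 210 with a counting interval of 37.2 to 8320, as only 1 read was left. Nucleotide and one-carbon genes rose in 16 of 26 cases and fell in 6 (16 and 7 over the list alone; adjusted p = 0.00659, adjusted p = 0.17 with an estimated correlation), among them the mitochondrial folate enzyme MTHFD2 (1.91-fold), with PHGDH 1.5-fold lower. Chaperones rose in 20 of 30 cases and fell in 4 (also over the list alone; adjusted p = 0.000565, adjusted p = 0.291 with an estimated correlation), led by HSPA4L (3.2-fold), with DNAJB4 1.75-fold lower. PMVK, PHGDH and DNAJB4 are on chromosome 1 as well, at -0.77, -0.58 and -0.81 in windows with medians of -0.45, -0.55 and -0.44.

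Other lists fell in MYC T58A. Of 44 matrix and protease genes 33 fell and 6 rose (also over the list alone; median -0.82, camera adjusted p = 5.32e-07, held at adjusted p = 0.0367 with an estimated correlation). The integrin ITGB8 fell 82-fold, the collagen COL5A1 59.2-fold and the protease MMP9 47.7-fold, and COL3A1 rose 23-fold (counting interval 9.59 to 72.1). Genes of the dedifferentiated state fell in 24 of 35 cases and rose in 8 (24 and 9 over the list alone; adjusted p = 0.000565, adjusted p = 0.0592 with an estimated correlation). Fibronectin FN1 fell 77.9-fold and TGFBI 32.2-fold, while ANKRD1 rose 2.52-fold. Of 15 neural crest and glial genes 13 fell and none rose (also over the list alone; median -3.57, adjusted p = 1.11e-06, adjusted p = 0.0574 with an estimated correlation), with TFAP2B at least 69.4-fold and the receptor ERBB3 84.4-fold lower. Melanocyte genes fell in 17 of 25 cases and rose in 4 (also over the list alone; adjusted p = 0.00833, adjusted p = 0.0987 with an estimated correlation), with S100B 64.1-fold lower (counting interval 27.2 to 199). The pigment enzyme DCT nevertheless rose 75.8-fold (25.6 to 370) and MITF 2.38-fold.

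Of 23 NF-kB and secretion genes 16 fell and 5 rose (also over the list alone; median -2.31, adjusted p = 0.000565, adjusted p = 0.0987 with an estimated correlation), with the cytokine IL1B 61.2-fold lower (counting interval 30.8 to 143) and the protease MMP10 9.15-fold higher. Of 39 interferon genes 25 fell and 5 rose (27 and 5 over the list alone; median -0.68, adjusted p = 0.000496, held at adjusted p = 0.0367 with an estimated correlation). IRF7 fell 69.3-fold (counting interval 23.3 to 339), GBP2 40.1-fold (15.4 to 149) and the class I antigen gene HLA-B 5.92-fold, and IFITM2 rose 1.52-fold. Hypoxia genes (14 of 20 lower, 3 higher), lysosome genes (16 of 29 lower, 3 higher) and MAPK output genes (21 of 34 lower, 9 higher) were lower with the same numbers over the list alone, and mitosis genes in 22 of 36 cases with 4 higher (23 and 4 over the list alone). Their adjusted p were 0.00848, 0.00467, 0.00848 and 0.00521, and with an estimated correlation adjusted p = 0.0592, 0.146, 0.291 and 0.31. Carbonic anhydrase CA9 fell 18.9-fold, CTSK 14.8-fold, the matrix protein TNC 21.3-fold and the kinesin KIF2C 2.27-fold, while MXI1, NPC1 and SPRY1 of the first 3 lists rose 3.21-fold, 1.51-fold and 12.1-fold, and UBE2S of the mitosis list rose 2.65-fold. NPC1 (0.6) rose less than its window on chromosome 18 (0.78). With the shifts of windows taken off, 17 of the 18 lists called in MYC T58A were called the same way, and that of MAPK output was not (adjusted p = 0.0681). Lists not called before were gained, which made 19.

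In all, 10862 genes (63.8%) differed between MYC T58A and Parental, 5129 higher and 5733 lower (limma, adjusted p under 0.05), 1241 and 2167 of them by at least 1 on the log2 scale, and 12374 (72.7%, chance 10%) had libraries that did not overlap. BRAF rose 1.37-fold and EGFR 1.2-fold, NRAS, AXL and SRC fell 1.39-fold, 1.66-fold and 1.49-fold, and DUSP6 did not pass the test (0.04, adjusted p = 0.501). NRAS (-0.47) fell no more than its window on chromosome 1 (-0.48), and SRC (-0.58) lies on chromosome 20 in a window with a median of -0.3. Among other cell types, 6 of 7 endothelial markers were lower and none higher (adjusted p = 0.0908 for the list), 5 of 8 fibroblast markers were lower and 2 higher (0.2), and of 10 keratinocyte markers 4 were lower and 3 higher (0.841). The keratinocyte median was 0.28, against a mean of -0.98 and a test direction of down. Of 3 immune markers LYZ fell 78.4-fold (counting interval 37.8 to 196) and CSF1R 3.92-fold. Of 13 mitochondrially encoded transcripts 3 were lower and none passed over the list alone (adjusted p = 0.44 for the list). Against a minimum change of 0.5 on the log2 scale 3973 genes were called.

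The libraries labelled shMYC1, in which MYC was higher and not lower than in Resistant, had SOX10 at 11890 ± 1140 normalized reads, 1440-fold above Resistant (log2 10.49, SE 0.2, adjusted p = 2.65e-16) and 2.25-fold above Parental (1.17, adjusted p = 0.000201). DUSP6 stood at 4886 ± 302, 5.69-fold above Resistant (2.51, SE 0.049, adjusted p = 3.02e-17) and close to the 4865 ± 79.4 of Parental (0, adjusted p = 0.957). IL6 was 637-fold lower than in Resistant at 3.06 ± 1.27, and CCL2 143-fold lower. Also among the genes that rose most were GAS7 (484-fold), the chloride channel ANO1 (334-fold), the neural crest cadherin CDH19 (235-fold) and the protocadherin PCDH1 (136-fold). Among those that fell most were the inflammasome gene NLRP2 (1040-fold, counting interval 287 to 8560), MYOCD, a smooth muscle coactivator (185-fold), and the muscle protein IGFN1 (149-fold).

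The Resistant libraries enter this comparison and that with Parental, so part of any opposite movement of lists arises without change. NF-kB and secretion genes were lower in 18 of 23 cases and higher in 3 (also over the list alone; median -2.45, camera adjusted p = 6.95e-07, held at adjusted p = 0.0354 with an estimated correlation). The receptor TNFRSF9 was 38-fold lower and IL1A 9.23-fold higher. ATF4 targets were lower in 20 of 25 cases and higher in 3 (also over the list alone; median -0.64, adjusted p = 1.72e-06, held at adjusted p = 0.0354 with an estimated correlation), NUPR1 by 32.5-fold, with VEGFA 1.31-fold higher. Interferon genes were lower in 29 of 39 cases and higher in 4 (also over the list alone; median -0.41, adjusted p = 9.35e-05, held at adjusted p = 0.0185 with an estimated correlation), the antiviral protein BST2 by 6.7-fold and IFI44L by 6.5-fold. MAPK output genes were higher in 26 of 34 cases and lower in 5 (also over the list alone; median 0.92, adjusted p = 1.07e-06, adjusted p = 0.108 with an estimated correlation), EGR3 by 319-fold (counting interval 109 to 1550) and EGR1 by 27.9-fold, with BMF 27.8-fold lower. Neural crest and glial genes were higher in 9 of 15 cases and lower in 3 (also over the list alone; median 1.99, adjusted p = 0.0171, adjusted p = 0.297 with an estimated correlation). SOX2 was 126-fold higher (counting interval 66.1 to 276) and NCAM1 4.52-fold lower.

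Other lists were higher in the libraries labelled shMYC1 than in Resistant, though not G1/S and DNA replication (adjusted p = 0.466), oxidative phosphorylation (0.521), nucleotide synthesis (0.0674) or sterol synthesis (0.056). MYC targets were higher in 33 of 57 cases and lower in 2 (also over the list alone; median 0.24, camera adjusted p = 1.32e-05, held at adjusted p = 0.0121 with an estimated correlation). HK2 was 3.31-fold and NOP16 1.96-fold higher, and TERT 1.87-fold lower. Mitosis genes were higher in 26 of 36 cases and lower in 3 (30 and 3 over the list alone; adjusted p = 3.07e-06, adjusted p = 0.21 with an estimated correlation), the centromere histone CENPA by 2.91-fold and the kinesin KIF20A by 2.01-fold. Glycolysis genes were higher in 20 of 28 cases and lower in 1 (21 and 1 over the list alone; adjusted p = 0.000176, adjusted p = 0.21 with an estimated correlation), the glucose carrier SLC2A1 by 2.13-fold, with PFKFB2 1.62-fold lower. Genes of the mitochondrial ribosome (25 of 44 higher, 1 lower, also over the list alone), chaperones (21 of 30 higher, 3 lower; 21 and 4 over the list alone), ribosome biogenesis (23 of 46 higher, 6 lower, also over the list alone) and the proteasome (15 of 30 higher, none lower, also over the list alone) were called too. Their adjusted p were 0.000176, 0.000821, 0.0022 and 0.00287, and with an estimated correlation adjusted p = 0.319, 0.323, 0.297 and 0.364. MRPS30 was 2-fold, CCT5 1.68-fold, PNO1 2-fold and PSMA7 1.86-fold higher. Cytosolic ribosomal protein genes were higher in 20 of 65 cases and lower in none (14 over the list alone; adjusted p = 0.00867, adjusted p = 0.73 with an estimated correlation). RPL37 was 1.79-fold higher, but the list's median of 0.12 became -0.01 under quantile normalization. The call rested on library 2 labelled shMYC1, and without it 10 genes were higher and 4 lower (median 0.02, adjusted p = 0.377). Genes of chromosomes 5 and 20 were higher as a whole in this comparison (medians 0.45 and 0.4), as the libraries labelled shMYC1 lacked the shifts of Resistant there. NOP16, KIF20A, MRPS30, CCT5 and RPL37 lie on chromosome 5 and PSMA7 on chromosome 20, and CENPA, HK2 and PNO1 in windows of chromosome 2 with medians of 0.38 to 0.42. With the shifts of windows taken off, all 13 lists called against Resistant were called the same way, MYC targets at adjusted p = 6.69e-05 (median 0.25) and chaperones at 0.00766.

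In all, 9713 genes (57.1%) differed between the libraries labelled shMYC1 and Resistant, 4596 higher and 5117 lower (limma, adjusted p under 0.05; 47.3% higher, and 38.9% under total-count scaling), 1066 and 1814 of them by at least 1 on the log2 scale, and 10226 (60.1%, chance 10%) had libraries that did not overlap. NRAS was 3.21-fold lower (2262 ± 122 against 7271 ± 469), MITF 2.31-fold lower and SRC 1.29-fold higher (0.36, with 0.27 for its window), and BRAF (0.03, adjusted p = 0.679) and EGFR (-0.11, adjusted p = 0.125) did not pass the test. EGFR did pass under quantile normalization (-0.15, adjusted p = 0.0225), total-count scaling (-0.18, 0.0109) and without Resistant library 1 (-0.15, 0.0442). AXL did not pass either (0.32, adjusted p = 0.256), but library 2 labelled shMYC1 stood apart from its group there, and without it AXL was higher by 0.68 (adjusted p = 2.97e-11). Fibroblast markers were lower in 5 of 8 cases and higher in 1 (adjusted p = 0.0594 for the list, and 0.039 to 0.0495 without Resistant library 3 or library 1 or 3 labelled shMYC1), keratinocyte markers lower in 6 of 10 and higher in 3 (0.144), and endothelial markers higher in 4 of 7 and lower in 2 (0.18). The immune markers CSF1R and CD68 were 18.1-fold and 2.2-fold lower and LYZ 18.1-fold higher. Mitochondrially encoded transcripts were lower in 6 of 13 cases and higher in none (8 lower over the list alone; median -0.38, adjusted p = 0.0509). That list was called without Resistant library 2 (adjusted p = 0.00638) or library 3 labelled shMYC1 (0.00731). With the shifts of windows taken off, 17 lists were called in place of 13, and the fibroblast and mitochondrially encoded lists were among those gained (0.0493 and 0.0353). Against a minimum change of 0.5 on the log2 scale 3206 genes were called.

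Between the libraries labelled shMYC1 and Parental, 6730 genes (39.6%) differed, 3350 higher and 3380 lower. Of these, 49.8% were higher, and 37.5% under total-count scaling. NRAS was lower than in Parental as well (log2 -1.43, adjusted p = 1.99e-12), and MITF did not pass the test (0.1, adjusted p = 0.346). Targets of p53 were higher in 20 of 27 cases and lower in 2 (median 0.39, camera adjusted p = 5.47e-06, held at adjusted p = 0.00954 with an estimated correlation), with 21 and 2 over the list alone. NF-kB and secretion genes were lower in 16 of 23 cases and higher in 2 (also over the list alone; median -0.85, adjusted p = 5.47e-06, adjusted p = 0.0815 with an estimated correlation). This comparison was added after the data were examined.

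**Figure D4:**
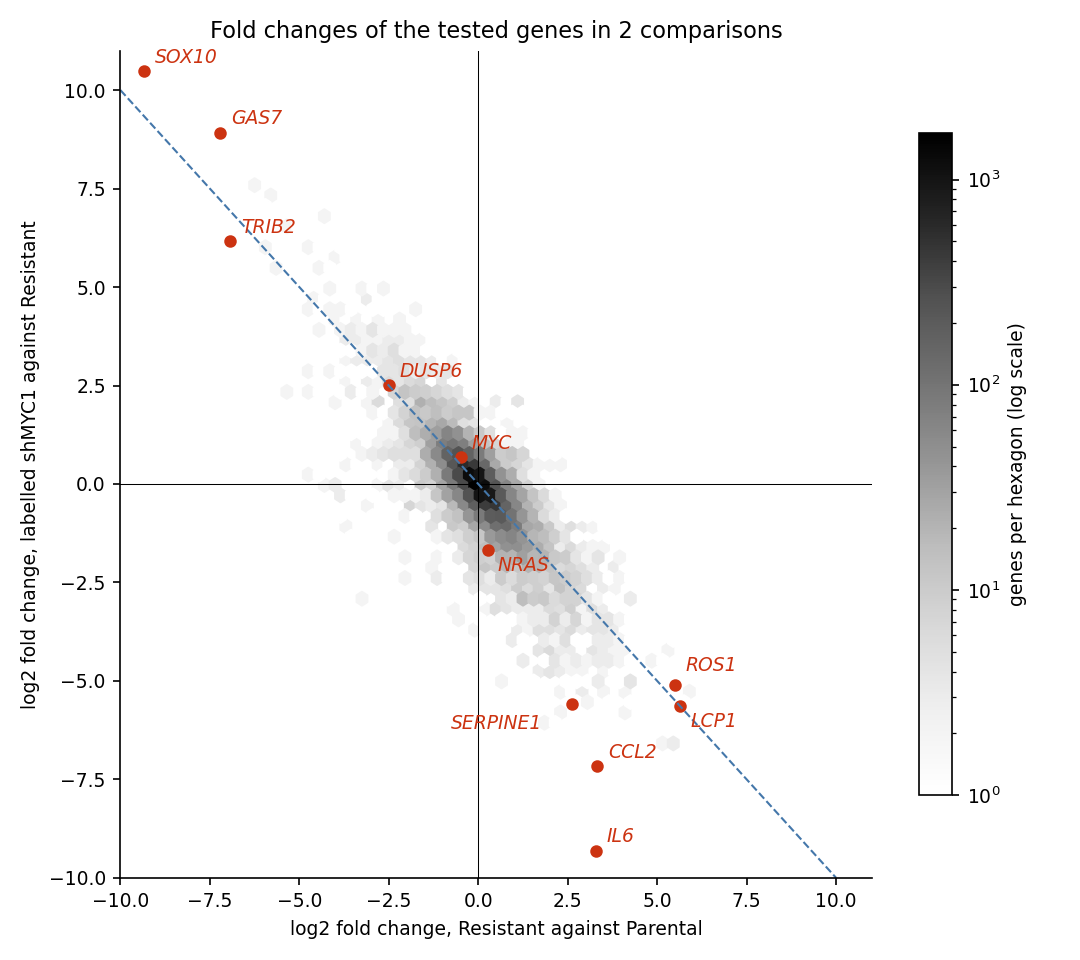
Log2 difference of each of the 17012 tested genes between Resistant and Parental (horizontal axis) and between the libraries labelled shMYC1 and Resistant (vertical axis), shaded by the number of genes in each hexagon. The genes lie along the dashed line of slope -1, with r = -0.77 across genes, where unchanged groups sharing the Resistant libraries would give -0.5.

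The libraries labelled shMYC2, with MYC 25.8-fold higher than in Resistant, differed from them in 13474 genes, more than were called in any of the other 3 main comparisons. PPP2R2C, a regulatory subunit of protein phosphatase 2A, was at 1245 ± 33.3 normalized reads and had none in Resistant (at least 427-fold higher). CD93, a surface receptor of endothelial and myeloid cells, stood at 16250 ± 631 (1180-fold higher), the limb transcription factor PITX1 at 3030 ± 205 (1570-fold, counting interval 719 to 4270), the muscle filamin FLNC at 33960 ± 1320 (1050-fold) and RP4-765C7.2 at 3477 ± 170 (1010-fold). PLXDC2, a plexin domain protein, was 1790-fold (counting interval 701 to 6590), CCL2 1630-fold (789 to 4050) and the myosin light chain MYL9 1580-fold (724 to 4300) lower. The adhesion molecule CADM1 was 1240-fold and complement C3 888-fold lower. SOX10 stayed near 0 (19.48 ± 3.74), and MITF was 21.7-fold lower than in Resistant at 172.7 ± 23 (log2 -4.44, SE 0.079, adjusted p = 8.07e-19).

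By list, NF-kB and secretion genes were lower in 21 of 23 cases and higher in 1 (21 and 2 over the list alone; median -2.34, camera adjusted p = 2.07e-05, adjusted p = 0.0933 with an estimated correlation). IL6 was 528-fold and the adhesion molecule ICAM1 445-fold lower, and IL1A 3.87-fold higher. Interferon genes were lower in 29 of 39 cases and higher in 6 (also over the list alone; median -1.6, adjusted p = 0.00112, adjusted p = 0.0735 with an estimated correlation). OAS2 was 574-fold (counting interval 159 to 4750) and MX2 235-fold lower, while IRF7 was at least 39.6-fold higher. ATF4 targets were lower in 18 of 25 cases and higher in 4 (also over the list alone; adjusted p = 0.0192, adjusted p = 0.373 with an estimated correlation), NUPR1 by 110-fold, with VEGFA 1.93-fold higher. Sterol and fatty acid genes were higher in 21 of 28 cases and lower in 4 (also over the list alone; median 0.6, adjusted p = 0.00059, adjusted p = 0.0933 with an estimated correlation). SCD was 6.23-fold and the cholesterol transfer protein STARD4 6.09-fold higher, while DHCR7 was 250-fold lower. Glycolysis genes were higher in 19 of 28 cases and lower in 6 (20 and 6 over the list alone; median 0.69, adjusted p = 0.00244, adjusted p = 0.373 with an estimated correlation). The lactate carrier SLC16A3 was 40.2-fold and lactate dehydrogenase LDHA 3.44-fold higher, and ARRDC4, which limits glucose uptake, 369-fold lower (counting interval 102 to 3050). Oxidative phosphorylation genes (26 of 34 higher, 3 lower, also over the list alone) and the mitochondrial ribosome (24 of 44 higher, 10 lower, also over the list alone) were called as well. Their adjusted p were 0.00519 and 0.0192, and with an estimated correlation adjusted p = 0.642 for both. PPARGC1B, a coactivator of mitochondrial genes, was 2.61-fold higher and its relative PPARGC1A 51.3-fold lower (counting interval 23.3 to 141), and MRPS5 was 2.84-fold higher and MRPL20 1.9-fold lower.

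MYC targets were higher in 22 of 57 cases and lower in 21 (also over the list alone; median 0.06, adjusted p = 0.435), and the sign of the median turned under total-count scaling (-0.08) and quantile normalization (-0.06). ODC1 was 7.13-fold, BOP1 4.5-fold and HK2 4.43-fold higher, while the aminoacyl-tRNA synthetase FARSA was 3.06-fold lower (-1.61, with -1.65 for its window on chromosome 19). Of markers of other cell types, keratinocyte genes were lower in 7 of 10 cases and higher in none (also over the list alone; median -2.91, adjusted p = 0.0192, adjusted p = 0.139 with an estimated correlation). DSP of the desmosome was 100-fold and ELF3 at least 40.2-fold lower. The fibroblast surface marker THY1 was 800-fold higher (counting interval 388 to 1990) at 1949 ± 39.8 and PDGFRL at least 26.5-fold lower, the endothelial receptor KDR was 5.61-fold higher and TEK 29.5-fold lower (counting interval 11.2 to 110). Among 13 mitochondrially encoded transcripts 5 were higher and 2 lower (4 and 2 over the list alone; adjusted p = 0.354 for the list).

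In all, 13474 genes (79.2%) differed between the libraries labelled shMYC2 and Resistant, 6155 higher and 7319 lower (limma, adjusted p under 0.05; 45.7% higher, and 38.8% under total-count scaling), 2283 and 4346 of them by at least 1 on the log2 scale, and 13836 (81.3%, chance 10%) had libraries that did not overlap. EGFR was 2.78-fold, DUSP6 2.35-fold and NRAS 1.29-fold higher and SRC 1.7-fold lower, and BRAF did not pass the test (-0.06, adjusted p = 0.357), though it was called lower under quantile normalization (-0.15, adjusted p = 0.0195) and total-count scaling (-0.2, 0.0034). AXL was 1.63-fold higher (adjusted p = 0.0138), a call lost with quantile normalization (0.33). The median log2 difference of all tested genes was -0.075, and it moved to -0.221 under total-count scaling and to 0.152 under quantile normalization, so smaller differences in this comparison depend on the scaling. Against a minimum change of 0.5 on the log2 scale 8206 genes were called.

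Taking both hairpin labels on average against Resistant, 12414 genes (73%) differed, 5675 higher and 6739 lower (45.7% higher, and 37.3% under total-count scaling). MYC was 6.44-fold higher (2.69, SE 0.055). For 5849 genes (34.4%, chance 2.38%) the 6 labelled libraries did not overlap with the 3 of Resistant. In each direction, 2393 genes were higher and 3034 lower with both labels, where independent lists would share 1663 and 2201. TRIB2 was 72.2-fold higher with the shMYC1 label and 44-fold with shMYC2, the neural adhesion gene NTM 21-fold and 107-fold, the plasminogen activator PLAT 24.9-fold and 18.5-fold, the endothelial proteoglycan ESM1 16-fold and 52.7-fold, and the neurotensin receptor NTSR1 22.2-fold (counting interval 9.27 to 69.8) and 1380-fold (591 to 4250). Lower with both were IL6, CCL2, IGFN1 (149-fold and 94.7-fold), the channel TRPC4 (63.6-fold and 242-fold) and ARMCX4 (54.4-fold and 1490-fold, the latter with a counting interval of 412 to 12300). The log2 differences correlated at r = 0.27 across genes with a covariance of 0.686, against 0.5 and 0.0243 for simulated unchanged groups that share the Resistant libraries, where at most 1 gene was called with both. Part of the excess in shared calls may come from the shared controls, since 3 Resistant libraries cannot be split into parts of 2. Changes particular to Resistant, as the common reference, would also be called the same way with both labels. Between the labels themselves 13370 genes differed, and 2753 genes were called in opposite directions against Resistant.

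Many genes that differed between Resistant and Parental were called the other way between the labelled hairpin libraries and Resistant. Such genes are termed moved back. MYC was not lower in these libraries. Any group that lacks the changes of Resistant would give such calls, whether or not it came from Resistant cells. Neither the independent lists nor the simulated unchanged groups test for that. Of the 4623 genes higher in Resistant than in Parental, 3184 (68.9%) were lower with both labels on average than in Resistant, and of the 4158 lower genes 2628 (63.2%) were higher (independent lists 1831 and 1387). With shMYC1 alone, a choice made after the data were examined, 3420 (74%) and 3006 (72.3%) moved back (independent lists 1391 and 1123). LCP1, KIAA1462, ROS1, the kinase DGKI and MYL9 led the genes that were higher in Resistant, 49.6-fold, 43.1-fold, 34.6-fold, 19.3-fold and 18.6-fold lower in the libraries labelled shMYC1, and SOX10, GAS7, TRIB2, ANO1 and PCDH1 led the others. For both labels the r across genes was -0.51 and the covariance -0.695, against -0.58 and -0.0241 in simulated unchanged groups. With shMYC1 alone they were -0.77 and -0.837, against -0.5 and -0.0241. Simulated groups gave no gene called in both comparisons, and part of the excess may come from the shared Resistant libraries. Both hairpin labels on average differed from Parental in 11838 genes, 5225 higher and 6613 lower (44.1% higher, and 34.8% under total-count scaling).

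Resistant and MYC T58A, each against Parental, shared 1739 higher and 1997 lower genes (independent lists 1394 and 1401), while 1554 genes were higher in Resistant and lower in MYC T58A and 1047 the reverse (independent lists 1558 and 1254). The shared genes with the largest changes were SOX10, GAS7, ANO1 (57.9-fold and 23.1-fold lower), ERBB3 (17.7-fold and 84.4-fold lower) and the class II antigen gene HLA-DRA (15.8-fold and 244-fold lower). Those higher in both were PLAC8 (10.1-fold and 18.1-fold), the synaptic gene RIMS2 (6.42-fold and 5.98-fold), the ligand WNT7B (5.91-fold and 6.88-fold) and the basement membrane gene NID2 (7.33-fold and 5.53-fold). AL161626.1 was also higher in both, but its call in Resistant (3.13, adjusted p = 0.0493) was lost without any 1 Parental library and without Resistant library 2 (2.79) or 3 (1.92). The log2 differences correlated at r = 0.27 with a covariance of 0.305, against 0.5 and 0.024 in simulated unchanged groups that share Parental. The same sign was seen in 55.5% of genes, against 66.6% in the simulation, in which no gene was called in both. Sharing the Parental libraries alone thus gave no shared calls there. Part of the excess may still come from it, since the simulation held no changed genes. Tested directly, 11532 genes differed between Resistant and MYC T58A, 6123 higher and 5409 lower in Resistant. MYC targets were lower in Resistant than in MYC T58A in 46 of 57 cases and higher in 2 (also over the list alone; median -0.47, camera adjusted p = 2.16e-10, held at adjusted p = 0.000603 with an estimated correlation). NF-kB and secretion genes were higher in 22 of 23 cases and lower in 1 (also over the list alone; median 2.74, adjusted p = 3.98e-09, held at adjusted p = 0.0163 with an estimated correlation).

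MYC T58A against Parental and both hairpin labels against Resistant share no library. Genes higher in MYC T58A and lower with the hairpin labels numbered 1801, and the reverse 1836, against 2032 and 1912 for independent lists, and calls in the same direction numbered 2097 higher and 2643 lower (independent lists 1711 and 2271). Their log2 differences correlated at r = 0.11 across genes (covariance 0.172, near 0 in simulated groups). With shMYC1 alone r was -0.12 (covariance -0.15), though counts of calls showed no such turn. Opposite calls then numbered 1567 and 1858 (independent lists 1543 and 1549) and calls in the same direction 1516 higher and 1928 lower (1386 and 1724). The same sign was seen in 50.2% of genes, against 49.9% in the simulation. The cytokine GDF15 rose 27.4-fold in MYC T58A and was 9.09-fold lower in the libraries labelled shMYC1, and FHL1, a LIM domain protein, rose 7.82-fold and was 12.2-fold lower. SOX10, GAS7 and the class II genes HLA-DRB1, HLA-DRA and HLA-DRB5 were lower in MYC T58A and higher in the libraries labelled shMYC1. HLA-DRB1 and HLA-DRB5 are close paralogs, and how reads were divided between them is uncertain.

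**Figure D5:**
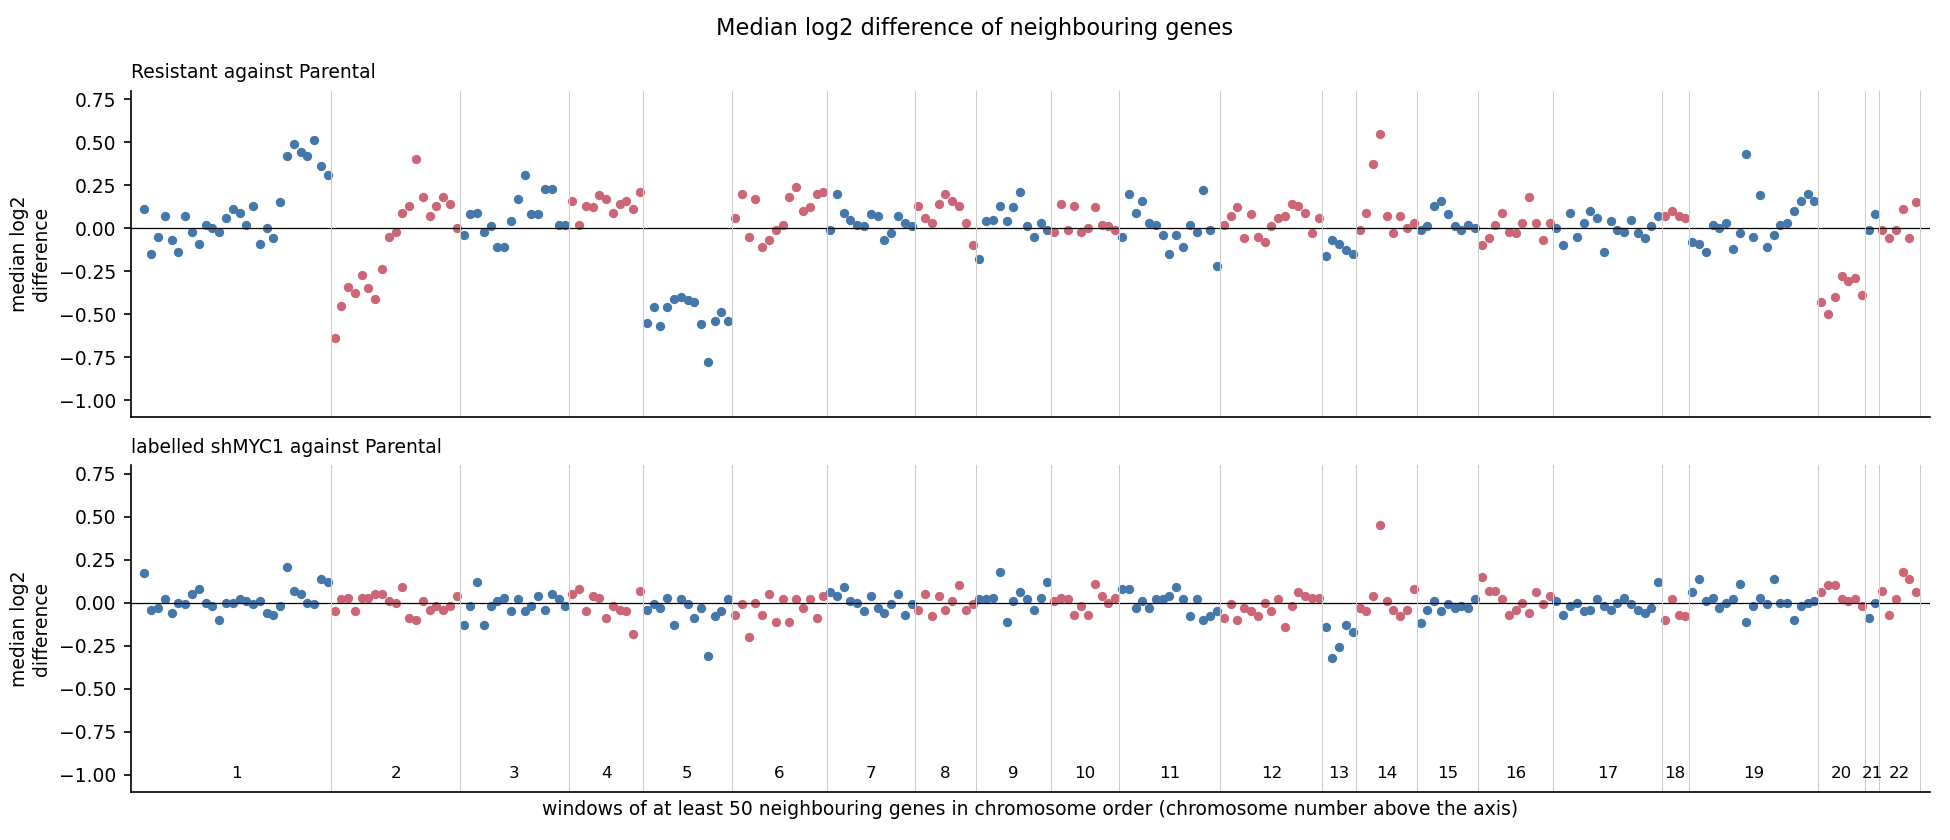
Median log2 difference in windows of at least 50 neighbouring tested genes along the chromosomes (horizontal axis, chromosomes in order), for Resistant minus Parental (top) and the libraries labelled shMYC1 minus Parental (bottom). All 13 windows of chromosome 5 lie between -0.78 and -0.4 and all 7 of chromosome 20 between -0.5 and -0.28 in Resistant, whereas in the libraries labelled shMYC1 they lie between -0.31 and 0.03 and between -0.02 and 0.1.

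Neighbouring genes also moved together. The 688 genes in 13 windows of chromosome 5 had a median log2 difference of -0.5 between Resistant and Parental, and the 361 genes in 7 windows of chromosome 20 one of -0.36. In the libraries labelled shMYC1 the medians against Parental were -0.05 and 0.03. Some shifts were shared, however: chromosome 13 was lower in all 5 windows in both (medians -0.14 in Resistant and -0.21 in the libraries labelled shMYC1), and a window of chromosome 14 was higher in both (0.55 and 0.45). In MYC T58A the medians against Parental were -0.46 on chromosome 1, -0.4 on chromosome 20 and 0.53 on chromosome 18. Over 262 windows the SD of the window medians was 0.197 for Resistant and 0.0775 for the libraries labelled shMYC1, each minus Parental, against at most 0.0729 and 0.0531 in 100 random gene orders. For MYC T58A it was 0.231, against at most 0.107. What the MYC T58A construct changed and what the history of that culture changed therefore cannot be told apart in its comparison with Parental. Gene order was taken from the GENCODE annotation, and these windows were set up after the data were examined.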

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

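The differences below were comparisons of the plan, and the count of genes called in opposite directions was added afterwards. Among the tests of explanations, those of scaling, of closeness to the parental state, of lower MYC from a hairpin, of depth, of shared Parental libraries, of higher MYC in both groups and both tests on windows of neighbouring genes were chosen after the result was seen.

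Resistant and MYC T58A cells were flagged because their effects against Parental differ from each other when tested directly. In all, 11532 genes differed between them (limma), and 2601 of these were called in opposite directions against Parental. MYC differed by -3.54 on the log2 scale (Resistant minus MYC T58A), DUSP6 by -2.54, EGFR by -0.58, BRAF by -0.38, SRC by 0.35, NRAS by 0.73 and AXL by 0.75. The real split of these 6 libraries called 11879 genes in a fit on them alone and the highest of the others 0, so 1 of 10 splits gave as many, and with 10 splits the share cannot go below 0.1.

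The hairpin labels were flagged because the 2 groups' effects against Resistant differ from each other. In all, 13370 genes differed between them, and 2753 were called in opposite directions against Resistant. MYC differed by -4.01 (shMYC1 minus shMYC2), NRAS by -2.05, EGFR by -1.58, SRC by 1.13, DUSP6 by 1.27 and MITF by 3.23. The real split called 12946 genes and the highest of the other splits 0, again 1 of 10.

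Splits of the other comparisons gave the following, each in a fit on its own libraries. For Resistant against Parental, MYC T58A against Parental and the labelled shMYC1 and shMYC2 libraries against Resistant the real splits called 9910, 11910, 8809 and 13594 genes, the highest other 0, and 1 of 10 splits gave as many. For both hairpin labels against Resistant 2 of 84 splits gave as many as the real 3013, but the highest other called 10995, so that share does not exclude other groupings. For both against Parental 2 of 84 gave as many as the real 980, and the highest other called 12543. In both cases that other split set the libraries labelled shMYC2 apart from all the rest, which points to a structure of the samples that the average of the labels hides.

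The first pattern weighed is that MYC was higher, not lower, in the libraries labelled shMYC1 than in Resistant. That difference (0.68, SE 0.064) is the pattern itself and so no separate test of whether the hairpin acted. Scaling between libraries is argued against, since the difference was 0.61 to 0.81 over 3 scalings. If the cells came from the Resistant population they would be expected to keep its chromosome-wide shifts, but the 27 windows that differed most between Resistant and Parental lay at a median position of 0.02 on a line from Parental (0) to Resistant (1; quartiles -0.05 and 0.13). Not all went that way: a window of chromosome 14 lay at 0.82 and one of chromosome 1 at 0.5, and chromosome 13 was lower than in Parental in all 5 windows in both groups (-0.14 and -0.21). Cells near the parental state would explain the pattern, and the 2426 genes that differed most between Resistant and Parental lay at a median position of 0.05 (quartiles -0.29 and 0.44). As these genes were picked by that difference, the position shows that the changes of Resistant were largely absent. It does not measure closeness to Parental in other genes. Against Parental 6730 genes (39.6%) differed, 1496 of them by at least 1 on the log2 scale. As a hypothesis, these libraries may come from cells that do not descend from the Resistant population sequenced here, whether by a label or by the history of the culture. Hairpin sequences or variants in the reads would test it and are not analysed here.

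The next pattern is that the libraries labelled shMYC2 lie far from the other 12. Depth is argued against, since their lowest total of 26.3 M reads (26332818) lies inside the range of the others (24.2 to 30.4). For RNA quality, their mitochondrially encoded share was 1.24 times that of the others (0.985% against 0.793%). Single libraries lay at 0.961% to 1.03%, against 0.52% to 0.989% in the others. That share does not measure RNA degradation, so RNA quality is left open. MYC was not lower than in Resistant, with a difference of 4.69. Whether the hairpin lowered MYC cannot be told from it, since Resistant would be no control for cells of another origin. Cells of another origin would spread whole stretches of chromosome, and the SD of window medians against Resistant was 2.06 times that of the widest pair without shMYC2 (0.611 against 0.297), although single genes also spread more widely (SD 2.28 against 1.29). Single windows may weigh heavily in it. Against Parental, windows of chromosome 19 lay at -5.76 and -1.99 and a window of chromosome 5 at -3.9, and all others between -1.57 and 0.94. The SD without these outlying windows was not computed. As a hypothesis, these libraries may come from a different line or a far diverged culture, and the design offers no sample that would tell these apart. Variants in the reads, set against those of A375, would test it and are not analysed here.

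The last pattern is that changes of Resistant and MYC T58A against Parental go the same way for more genes than independent lists give. The shared Parental libraries alone are argued against, since the covariance was 0.305 and at most 0.0258 in simulated groups. A higher MYC transcript in both groups is argued against by -0.49 for MYC in Resistant. MYC protein was not measured here, so higher protein or activity in both groups is left open. Chromosome 20 was lower in both groups (medians -0.36 in Resistant and -0.4 in MYC T58A), and how many shared calls come from it was not counted. The shifts of chromosome 5 (-0.5 and -0.03) and chromosome 1 (0.09 and -0.46) were not shared. Loss of the SOX10 state could be shared, as 36% of the melanocyte list was called the same way in both against 22% of all tested genes. That list holds SOX10 itself, whose fall in both groups raised the idea. Calls in either direction were counted, among them that of MITF, which was higher in both groups. A permutation test of that share against lists matched by expression gave p = 0.057, which leaves the explanation open.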

How the results depend on the processing

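Total-count scaling, edgeR, fits without the libraries labelled shMYC2, shMYC1 alone, and list tests less the shifts of windows of neighbouring genes were chosen after the data were seen. Over the alternatives run, 487 values that answer a comparison kept their direction and side of the threshold (or stayed within 1.5 times the main count), 23 moved, 6 fell short of the threshold and 1 reversed. Of the values for named genes, 10739 were the same, 113 fell short, 6 newly passed and 3 reversed.

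A minimum log2 change of 0.5 asks more by construction and gave fewer genes: 2541 for Resistant against Parental, 3973 for MYC T58A against Parental, 3206 and 8206 for shMYC1 and shMYC2 against Resistant, 5505 for both labels on average, 4950 for Resistant against MYC T58A, 7972 between the labels and 4575 for both labels against Parental. With it 1660 genes were called the same way with both labels and 1571 moved back, against 5427 and 5812, and MYC no longer passed in Resistant (-0.49) or in shMYC1 against Parental (0.2). Leaving out single libraries gave 7864 to 8405, 10064 to 10305, 8925 to 9640 and 13046 to 13179 genes in the 4 main comparisons.

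MYC in shMYC1 against Parental ranged from 0.15 to 0.24 as single libraries were left out. The call was lost without Parental library 2 or 3 or library 2 labelled shMYC1, and under total-count scaling (0.14). MYC ranged from -0.6 to -0.42 in Resistant, 3.02 to 3.1 in MYC T58A, and 0.61 to 0.81 and 4.55 to 4.76 in shMYC1 and shMYC2.

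The list tests depended most on the method. With an estimated correlation 3, 3, 4, 0 and 1 lists were called for the 4 main comparisons and the average of both labels, against 13, 18, 13, 8 and 14, and less the shifts of windows 14, 19, 17, 8 and 15. With fry there were 25, 30, 27, 26 and 27, but fry asks whether a list changed at all and camera whether it changed more than other genes, so with most genes called the 2 counts answer different questions. For that average 9 lists were called under quantile normalization, a filter of at least 50, and total-count scaling. The correlation of MYC T58A with both labels turned from 0.11 to -0.12 with shMYC1 alone. CD68 in shMYC2 turned from -0.75 to 0.3 under quantile normalization, and BRAF in shMYC1, not called at 0.03, was -0.04 under total-count scaling and -0.03 to 0.07 as libraries were left out (-0.03 without Resistant library 1). For these moves the cause was not tested.

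limma-voom was not run, since the plan put limma without robust in its place for normalized values, and treat in place of glmTreat. No paired analysis was possible because the columns carry running numbers and no replicate numbers. In simulations with few changed genes, depth limited little for genes with a mean of at least 50 in the reference group. Of these, genes changed 1.5-fold were recovered in 88% to 98% of cases. Recovery of genes below that level was not simulated.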

Other observations

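These observations were chosen after the values were seen, and no explanation is given for them.

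The 5 genes CIITA, CD74, HLA-DRA, HLA-DPA1 and HLA-DMA were highest in the libraries labelled shMYC1 and next in Parental. CIITA stood at 687 in Parental, 140.1 in Resistant, 1511 in the libraries labelled shMYC1, 24.47 in those labelled shMYC2 and 7.567 in MYC T58A. CD74 stood at 8888, 2633, 31920, 49.33 and 177.8, HLA-DRA at 1984, 125.3, 6963, 21.22 and 7.566, HLA-DPA1 at 1890, 1097, 4511, 14.34 and 140.2, and HLA-DMA at 315.7, 206.1, 854, 9.704 and 73.75 in the same order. The call of HLA-DMA in Resistant against Parental was lost without Parental library 2 or Resistant library 2 (-0.58).

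In the libraries labelled shMYC2, 251 genes were below 5 normalized reads in all 3 libraries and at least 100 in all 12 others, and no other group had more than 1 such gene. Of these, 72 (28.7%) had zinc finger symbols, against 360 of 10154 expressed genes (3.55%), and 63 of the 72 lay on chromosome 19. The class was picked after these genes were seen. In these libraries 1042 genes had no read in all 3, against 127 to 311 in the other groups. MTAP stood at 144.2 ± 8.81 there, against 5258 in Resistant and 7359 in Parental.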
